A study of Caenorhabditis elegans with 16 samples.

How the data were processed

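RNA of whole day 1 adults was measured in 16 libraries from 4 strains, with 2 libraries for each strain and condition. Per the labels' protocols, synchronised animals were moved to 2 °C for 6 h at 18 to 20 h after the L4 stage and then returned to 20 °C, polyadenylated RNA was sequenced, and the company that built the libraries is named but its kit is not. Groups were taken from the sample titles, because the treatment field gives cold stress for all 16 libraries, the controls included. The protocol mentions more biological replicates than the 2 per group that were deposited. The batch field equals the replicate number, so the 2 numbers stand for 2 batches that each hold every group once.

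The deposited values are raw counts per gene, 1 file per library, with whole numbers of at least 0 and no normalisation by the authors that the values show. Reads were mapped with RNA STAR to WBcel235, per the file headers and the labels. The counting program, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Each file lists 46759 gene IDs. Gene names, positions and lengths came from the Ensembl release 115 annotation of WBcel235, which held 46532 of the IDs and left 227 without a name, with 0.0848% to 0.106% of the counts. Ribosomal RNA took 0.258% to 0.479% of counts and the mitochondrial genome 0 counts, so mitochondrially encoded transcripts could not be tested.

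Library totals ran from 48463805 to 98107540 counts. A count of 0 leaves open a level of up to 3 counts, or 0.0306 to 0.0619 CPM by library, and such limits cover counting error only. CPM values used library totals scaled by TMM factors. Fold changes against a group with 0 counts in every library depend on the prior count, so medians of lists that hold such genes were also computed with them at a bound of 3 counts over the group.

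Genes were tested in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after filterByExpr with its minimum count of 10 kept 17461 genes. A quasi-likelihood model with robust estimation and 1 coefficient for each of the 8 groups was fitted to all libraries, and 16 contrasts were tested, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. They were cold against control in each strain, each strain against N2 and the double mutant label against the sgk-1 strain in each condition, and the 4 differences between cold responses. Standard errors of log2 fold changes are those of the fit. Genes of 46 lists out of 47 fixed before the data were examined were set against all other genes with camera, two-sided, at a preset correlation of 0.01, adjusted over the lists of a contrast. Of these 736 tests 242 passed, and 32 passed with a correlation estimated from the residuals, all 32 among the 242. Members past the threshold were counted over all genes and, separately, adjusted over the list alone.

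The rule for named genes, also fixed before the data were examined, took sgk-1 and pqm-1, the 10 higher and 10 lower genes with the largest fold change among called genes with a mean of at least 5 CPM and separated replicates, up to 4 called members of each list by adjusted p, and a panel of 28 genes. It gave 1806 gene and contrast pairs that were called, more than a text can hold. Those named as called were then picked for keeping their call in every refit, except where a minimum fold change was asked for, and this step was taken after the refits were seen. The stability of named genes is therefore a property of how they were picked: 30.6% of the 1806 pairs, and 54.7% of all 25073 calls in the 16 contrasts counting left-out libraries alone, lost their call in at least 1 refit.

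Fits were repeated with RLE size factors, with a DESeq2 1.42.0 Wald test, without the filter, with the replicate number as a block, with only the compared groups, with a log2 fold change of at least 1, and without each library in turn. A lone library left in a group was then assumed to vary like the other groups. A fit with the block in which each library's trend over gene length (a polynomial of degree 3 over the 99.4% of tested genes with a known length) was removed was added after the data were seen, as were the list tests, the overlap and the double mutant comparison without each library. GC content was not analysed here, since no genome sequence was used.

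The steps were tested on simulated data first, drawn from the means of 16982 genes with 200 genes changed. For cold in N2 they recovered 68 of 100 genes changed by a log2 value of 1 and 97 of 100 changed by 2, with 11 false calls among 176. For the difference in cold response of the sgk-1 strain they recovered 35 and 83 of 100, with 5 false calls among 123. In the contrast left unchanged, cold in the sgk-1 strain, edgeR called 0 genes. Camera called 1 of 1 shifted lists and 0 of 20 unshifted ones. Whether replicate numbers pair the groups was checked by correlating replicate differences over genes between groups. Across 28 pairs of groups the correlation ran from -0.065 to 0.241 with a median of 0.009, and 5 were above 0.1.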

Results

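Polyadenylated RNA of whole nematodes (Caenorhabditis elegans) was sequenced in 16 libraries from 4 strains, with 2 libraries in each of 8 groups. Each strain was sampled as day 1 adults kept at 20 °C (control libraries) and as adults exposed to 2 °C for 6 h (cold libraries). The strains were N2, the wild type, and strains labelled sgk-1(ok538), pqm-1(ok485) and the double mutant of both. SGK-1 is a serum- and glucocorticoid-inducible kinase that acts downstream of insulin and TORC2 signalling. PQM-1 is a zinc finger transcription factor of the intestine. Each library held 48463805 to 98107540 counts assigned to genes. A count of 0 leaves open a true level of up to 3 counts, or 0.0306 to 0.0619 CPM (counts scaled to a common library total). The labels place the exposure 18 to 20 h after the L4 stage but do not say how long after the return to 20 °C the animals were collected. Fold changes are log2 values ± back-calculated standard error (n = 2 libraries per group throughout), and CPM values are mean ± SD. Of 163 genes named, 48 overlap another gene, 40 of them one on the opposite strand. The strand setting of the counting is not given in the sources used here, so their counts are uncertain to that extent, as are those of near-identical copies among the msp, pals and pud genes. Genes were picked from those that a rule fixed in advance gave. Those named as higher or lower were limited, after the refits were seen, to genes that kept their call in each of them.

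The targeted genes were examined first. Transcripts of sgk-1 (WBGene00004789, WBcel235 chromosome X, 16254842 to 16262122) stood at 20.9 ± 1.24 CPM in N2 control libraries and 33.4 ± 1.56 CPM in N2 cold libraries. They stood at 4.02 ± 0.242 and 8.12 ± 0.0524 CPM in the sgk-1 strain and at 3.1 ± 0.0586 and 6.29 ± 1.11 CPM in the libraries labelled double mutant. The log2 difference from N2 in control libraries was -2.38 ± 0.14 for the sgk-1 strain and -2.75 ± 0.14 for the double mutant label (edgeR adjusted p = 2.44e-07 and 1.26e-07). Transcripts of pqm-1 (WBGene00004096, chromosome II, 11150391 to 11152595) did not follow the labels. They were lower in pqm-1-labelled control libraries (3.84 ± 0.162 CPM) than in N2 control libraries (10.2 ± 1.7 CPM). In pqm-1-labelled cold libraries they stood at 42.1 ± 1.77 CPM, where N2 had 36.4 ± 1.02 CPM. In the libraries labelled double mutant, pqm-1 was at 9.72 ± 0.691 CPM without and 34.7 ± 1.14 CPM with cold, and the sgk-1 strain had 26.4 ± 5.21 and 14.4 ± 3.02 CPM. Counts summed over the whole gene therefore do not show the pqm-1 deletion, and the part of the gene that the ok485 allele removes is not given in the sources used here. The 8 libraries concerned are called pqm-1-labelled and double-labelled throughout, and directions in them rest on the labels.

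**Figure D1:**
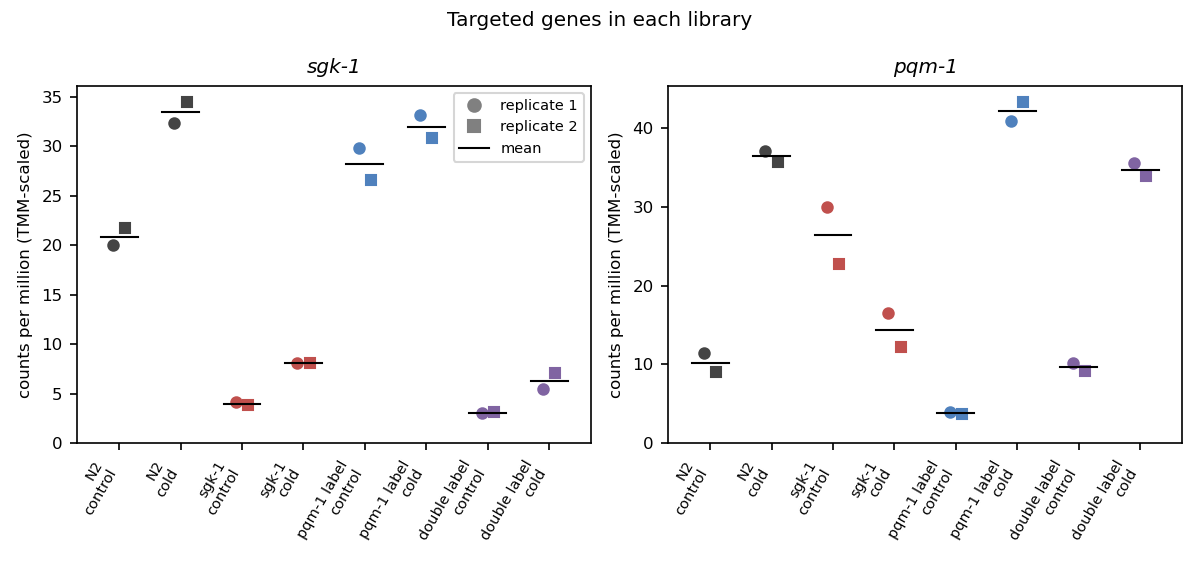
CPM of sgk-1 (left) and pqm-1 (right) on a linear axis in each of the 16 libraries, by group; circles are replicate 1, squares replicate 2, and the bar is the mean of the 2 libraries. Every library of the sgk-1 strain and of the double mutant label lies at or below 8.15 CPM of sgk-1 while N2 lies at or above 20 CPM, and the pqm-1-labelled cold libraries lie at 40.8 and 43.3 CPM of pqm-1.

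Samples separated by cold on the first principal component (32.8% of the variance of log CPM). The pqm-1-labelled libraries parted from the rest on the second (20.5%). Replicates differed by a median of 0.151 to 0.42 log2 units per gene, and the 2 double-labelled control libraries differed most. In these, transcripts of the yolk genes took 5.45% of counts in replicate 1 and 13% in replicate 2, and expression changed with gene length at slopes of -0.204 and 0.148 log2 units per doubling. Replicates, which are separate cultures, differed by more than counting error alone gives (chi-square of 12.78 to 310.7 per degree of freedom).

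Cold exposure of N2 raised a lysozyme, infection response genes and HIF-1 target genes, and lowered elongases and a peptide transporter that serve fatty acid synthesis and nutrient uptake. The lysozyme gene lys-3 (8.41 ± 0.54), the cytochrome P450 gene cyp-13A5 (7.84 ± 0.51) and the poly(ADP-ribose) glycohydrolase gene parg-2 (6.80 ± 0.21) rose. So did the infection response genes irg-2 (5.02 ± 0.30) and irg-1 (4.01 ± 0.25). The fatty acid elongase genes elo-6 (-5.49 ± 0.25), elo-5 (-4.52 ± 0.12) and elo-2 (-4.23 ± 0.14) fell, of which elo-5 and elo-6 make branched-chain fatty acids. The hydroxyacyl-CoA dehydrogenase gene hacd-1 (-5.88 ± 0.19) and the haem transporter gene hrg-4 (-5.75 ± 0.53) fell too. In all, 1715 genes were higher and 1535 lower in N2 cold than in N2 control libraries out of 17461 tested. These became 2017 and 2174 with a trend over gene length removed and the replicate number as a block, and 2866 and 2887 when only these 4 libraries were fitted. Without N2 control replicate 2 lys-3 was at 9.68. The value of hrg-4 was -8.31 without N2 cold replicate 2 (N2 cold libraries at 0.406 ± 0.48 CPM).

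On WBcel235, lys-3 (WBGene00003092, chromosome V, 10282100 to 10283544), elo-5 (WBGene00001243, chromosome IV, 5374616 to 5377117), elo-6 (WBGene00001244, chromosome IV, 5386629 to 5388559) and rhy-1 (WBGene00012324, chromosome II, 9161379 to 9163448) are protein-coding genes. Of the lists fixed in advance, those for desaturation, oxidation and hypoxia passed with an estimated correlation in N2 and the others below did not. Of 25 fatty acid desaturation and membrane fluidity genes, 1 were higher and 9 lower (2 and 9 adjusted over the list alone, camera adjusted p = 5.71e-06, adjusted p = 0.0272 with an estimated correlation). The replicate number as a block made 2 of them higher, and the delta-9 desaturase gene fat-5 (-3.71 ± 0.45) was among those that fell. Of 31 fatty acid oxidation genes, 9 were higher and 15 lower (10 and 16 adjusted over the list alone, camera adjusted p = 4.24e-05, adjusted p = 0.0179 with an estimated correlation). The peroxisomal oxidase gene acox-1.4 (-3.14 ± 0.17) and the transporter gene pmp-5 (-2.41 ± 0.14) fell and acox-3 (1.98 ± 0.10) rose. Of 17 hypoxia response genes, 6 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 3.72e-06, adjusted p = 0.0179 with an estimated correlation). Those that rose included the cyanoalanine synthase gene cysl-2 (2.1 ± 0.10), the nuclear receptor gene nhr-57 (2.96 ± 0.17), the HIF-1 regulator rhy-1 (1.99 ± 0.13) and the carbonic anhydrase gene cah-4 (1.67 ± 0.10). Of 31 innate immune effectors, 15 were higher and 7 lower (16 and 9 adjusted over the list alone, camera adjusted p = 0.000283, adjusted p = 0.294 with an estimated correlation). A further member that rose was C17H12.8 (2.60 ± 0.26). Of 34 autophagy and lysosome genes, 13 were higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.294 with an estimated correlation). They included the autophagy receptor gene sqst-1 (2.99 ± 0.22) and hlh-30 (1.63 ± 0.23), the worm TFEB. Of 22 intestine genes, 4 were higher and 9 lower (4 and 10 adjusted over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.243 with an estimated correlation). The peptide transporter pept-1 (-3.96 ± 0.16) and the acid phosphatase pho-1 (-2.42 ± 0.13) were lower. Of 65 UDP-glucuronosyl transferases, 14 were higher and 30 lower (14 and 36 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.78 with an estimated correlation). They ran from ugt-63 (-5.68 ± 0.26) and ugt-22 (-3.85 ± 0.18) to ugt-54 (3.43 ± 0.19) and ugt-29 (2.65 ± 0.10). Of 136 collagens, 6 were higher and 40 lower (8 and 47 adjusted over the list alone, camera adjusted p = 0.000346, adjusted p = 0.48 with an estimated correlation). One that fell was col-179 (-3.0 ± 0.13).

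In the sgk-1 strain cold lowered fatty acid desaturation and oxidation genes, the elongase genes among them. The other lists below, such as sperm and cuticle genes (markers of other tissues and stages), did not pass with an estimated correlation. Genes that rose included lys-3 (7.30 ± 0.43), parg-2 (6.68 ± 0.23), irg-2 (4.70 ± 0.29) and the aspartic protease gene asp-17 (6.16 ± 0.34). Genes that fell included elo-6 (-4.50 ± 0.24), elo-2 (-3.76 ± 0.13), elo-5 (-3.44 ± 0.11), hacd-1 (-3.74 ± 0.17) and hrg-4 (-4.64 ± 0.47). Of 34 major sperm proteins, 25 were higher and 0 lower (29 and 0 adjusted over the list alone, camera adjusted p = 1.17e-08, adjusted p = 0.387 with an estimated correlation), for example msp-10 (1.12 ± 0.20). Of 24 sperm genes, 9 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.368 with an estimated correlation), for example gsp-3 (1.43 ± 0.19). Of 24 cuticle and moulting genes, 11 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.00662, adjusted p = 0.353 with an estimated correlation). The collagen gene sqt-1 (1.85 ± 0.24) and the protease gene dpy-5 (1.94 ± 0.22) rose. Of 24 intracellular pathogen response genes, 3 were higher and 12 lower (3 and 13 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.364 with an estimated correlation). Among those that fell was pals-6 (-3.04 ± 0.35). Among 25 fatty acid desaturation and membrane fluidity genes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 3.91e-08, adjusted p = 0.0144 with an estimated correlation). Among 31 fatty acid oxidation genes, 5 were higher and 15 lower (6 and 16 adjusted over the list alone, camera adjusted p = 3.35e-07, adjusted p = 0.0098 with an estimated correlation). Transporter gene pmp-5 (-2.12 ± 0.14) and oxidase gene acox-1.3 (-2.12 ± 0.15) were lower. Of 25 cytosolic chaperones, 6 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.44 with an estimated correlation). They included hsp-70 (1.33 ± 0.23) and hsp-16.41 (1.53 ± 0.25). Of 19 osmotic and epidermal stress genes, 11 were higher and 4 lower (13 and 4 adjusted over the list alone, camera adjusted p = 0.005, adjusted p = 0.387 with an estimated correlation). The antimicrobial peptide gene cnc-4 (3.48 ± 0.26) was higher and the inositol transporter gene hmit-1.1 (-1.81 ± 0.19) lower. Among 22 intestine genes, 3 were higher and 10 lower (4 and 11 adjusted over the list alone, camera adjusted p = 5.67e-07, adjusted p = 0.155 with an estimated correlation), with pept-1 (-3.07 ± 0.15) and pho-1 (-2.25 ± 0.13) lower. The totals were 1867 genes higher and 1137 lower. They became 2058 and 2140 in a fit, added after the data were seen, that took out each library's trend over gene length and blocked on the replicate number. Leaving out 1 library gave 1998 without sgk-1 control replicate 2, 1777 without sgk-1 cold replicate 1 and 1985 without sgk-1 cold replicate 2.

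In pqm-1-labelled libraries cold raised a lysozyme and an infection response gene and lowered elongase genes, and the lists below did not pass with an estimated correlation. The genes lys-3 (8.03 ± 0.47), cyp-13A5 (6.81 ± 0.46), irg-2 (4.59 ± 0.29), the sodium-proton exchanger gene nhx-6 (9.25 ± 0.50) and the insulin pathway target dod-3 (5.16 ± 0.40) rose. The genes hacd-1 (-5.78 ± 0.19), elo-5 (-5.19 ± 0.12), elo-6 (-4.59 ± 0.24), elo-2 (-4.22 ± 0.14) and the glycine cleavage gene gcsh-1 (-5.44 ± 0.37) fell. Of 18 phosphatidylcholine and one-carbon metabolism genes, 2 were higher and 9 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.135 with an estimated correlation). The S-adenosylmethionine synthetase gene sams-1 (-3.29 ± 0.18) and the choline phosphotransferase gene cept-1 (-1.45 ± 0.13) were lower. Of 26 DAF-16 activated genes, 11 were higher and 3 lower (12 and 5 adjusted over the list alone, camera adjusted p = 0.000788, adjusted p = 0.135 with an estimated correlation). The catalase gene ctl-2 (1.79 ± 0.10) and the transhydrogenase gene nnt-1 (2.99 ± 0.26) were higher. Of 25 SKN-1 and phase II detoxification genes, 10 were higher and 5 lower (13 and 6 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.263 with an estimated correlation). They included nit-1 (3.76 ± 0.14) and gst-13 (1.88 ± 0.13). Among 31 innate immune effectors, 15 were higher and 4 lower (16 and 5 adjusted over the list alone, camera adjusted p = 0.000159, adjusted p = 0.235 with an estimated correlation), with sysm-1 (4.05 ± 0.30) higher. Among 24 intracellular pathogen response genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000709, adjusted p = 0.263 with an estimated correlation), with pals-26 (4.17 ± 0.29) and skr-3 (1.87 ± 0.20) higher. Of 25 fatty acid desaturation and membrane fluidity genes, 3 were higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.0739 with an estimated correlation). Of 31 fatty acid oxidation genes, 13 were higher and 15 lower (14 and 16 adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.161 with an estimated correlation), with acox-3 (3.75 ± 0.10) higher and acox-1.3 (-3.36 ± 0.16) lower. Among 136 collagens, 5 were higher and 41 lower (5 and 47 adjusted over the list alone, camera adjusted p = 0.00055, adjusted p = 0.42 with an estimated correlation), with col-120 (-3.27 ± 0.33) lower. Among 34 major sperm proteins, 0 were higher and 6 lower (0 and 18 adjusted over the list alone, camera adjusted p = 0.000709, adjusted p = 0.592 with an estimated correlation). Of 22 intestine genes, 4 were higher and 8 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.000709, adjusted p = 0.27 with an estimated correlation). In this strain 1833 genes were higher and 1439 lower after cold, or 2137 and 2199 with the length trend removed and the replicate block.

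In double-labelled libraries cold raised a lysozyme and infection response genes and lowered elongase genes, and again the lists below did not pass with an estimated correlation. Genes that rose were lys-3 (8.84 ± 0.51), nhx-6 (8.89 ± 0.55), parg-2 (7.25 ± 0.22), irg-1 (5.10 ± 0.26), irg-2 (5.09 ± 0.29) and dod-3 (4.73 ± 0.39). Without double-labelled control replicates 1 or 2, nhx-6 was at 7.90 or 10.87. Genes that fell were ugt-63 (-4.46 ± 0.24), gcsh-1 (-3.79 ± 0.34), elo-6 (-3.53 ± 0.23), elo-5 (-3.33 ± 0.11), hacd-1 (-3.30 ± 0.16) and fat-5 (-3.77 ± 0.38). Of 31 innate immune effectors, 13 were higher and 2 lower (13 and 6 adjusted over the list alone, camera adjusted p = 2.39e-05, adjusted p = 0.256 with an estimated correlation). With the replicate block 4 were lower, and the lectin gene clec-67 (2.04 ± 0.15) was higher. Of 24 intracellular pathogen response genes, 9 were higher and 0 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.000638, adjusted p = 0.32 with an estimated correlation). The genes cul-6 (2.56 ± 0.21) and skr-3 (2.14 ± 0.20), parts of a ubiquitin ligase, were higher. The immune median was 0.74 (0.20 with members at 0 counts at their bound) and the pathogen median 1.51 (0.83 without them). Among 26 DAF-16 activated genes, 10 were higher and 3 lower (13 and 5 adjusted over the list alone, camera adjusted p = 0.0327, adjusted p = 0.32 with an estimated correlation), including ctl-2 (1.62 ± 0.10). Among 25 SKN-1 and phase II detoxification genes, 8 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0129, adjusted p = 0.32 with an estimated correlation), including gst-4 (1.39 ± 0.18). Among 25 fatty acid desaturation and membrane fluidity genes, 1 were higher and 6 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.000215, adjusted p = 0.109 with an estimated correlation). Among 31 fatty acid oxidation genes, 6 were higher and 13 lower (7 and 18 adjusted over the list alone, camera adjusted p = 0.00635, adjusted p = 0.109 with an estimated correlation). The oxidase gene acox-3 (2.19 ± 0.10) and the carnitine palmitoyltransferase gene cpt-4 (3.39 ± 0.17) were higher and pmp-5 (-1.83 ± 0.14) lower. Here 1536 genes were higher and 1058 lower, or 1826 and 2479 with the length trend removed and the replicate block. The total became 4589 without double-labelled control replicate 2 and 1636 without double-labelled cold replicate 1.

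**Figure D2:**
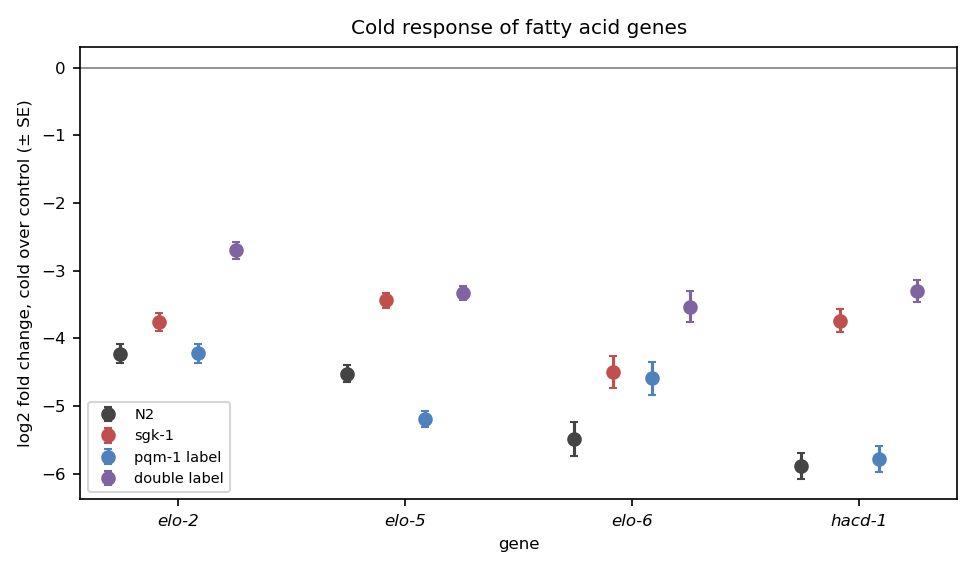
Log2 fold change of cold over control libraries (vertical axis, linear in log2 units) for elo-2, elo-5, elo-6 and hacd-1 in the 4 strains; points are the fitted values and bars 1 standard error (n = 2 libraries per group). All 16 values lie below 0, from -2.70 (elo-2, double mutant label) to -5.88 (hacd-1, N2).

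Cold responses overlapped between strains more than independent lists would. The same 755 genes were higher and 501 lower in all 4 strains, where independent lists of these sizes would share 1.69 and 0.499. No control library is common to any pair of these comparisons. Besides lys-3, irg-2, cyp-13A5 and parg-2 the shared genes that rose included F33H12.7 (6.78 ± 0.48) and srlf-34 (7.19 ± 0.32) (values for N2, F33H12.7 at 7.86 without N2 control replicate 2). Those that fell included the sodium-calcium exchanger gene ncx-7 (-4.84 ± 0.27), the scavenger receptor gene scav-4 (-4.41 ± 0.20) and gcsh-1 (-5.98 ± 0.40) as well as the elongase genes. Between N2 and the sgk-1 strain, 1031 genes were higher and 785 lower in both (183 and 100 for independent lists) and 66 went in opposite directions. Opposite calls numbered 36 between N2 and pqm-1-labelled, 44 between N2 and double-labelled and 162 between sgk-1 and pqm-1-labelled libraries.

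Without cold, the sgk-1 strain differed from N2 by high levels of intracellular pathogen response genes and innate immune effectors and by low levels of major sperm protein genes. The decapping family gene eol-1 (6.36 ± 0.33), pals-14 (7.62 ± 0.52), pals-6 (5.26 ± 0.42), pals-26 (4.67 ± 0.34), the arginine kinase gene argk-1 (7.72 ± 0.35) and B0507.8 (8.47 ± 0.39) were higher. The value of pals-14 rests on near-zero N2 counts (0.111 ± 0.158 CPM) and was 13.86 without N2 control replicate 2. Lower were pud-4 (-4.79 ± 0.17) and pud-3 (-4.75 ± 0.16), as in the other strains. So were the glucocerebrosidase gene gba-4 (-4.75 ± 0.52) and the sphingomyelinase gene asm-3 (-4.33 ± 0.32). The saposin-like gene spp-17 (-4.79 ± 0.28), the dehydrogenase gene dhs-26 (-3.64 ± 0.32) and the lysosomal lipase gene lipl-5 (-2.99 ± 0.33) were lower as well.

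Among these genes are eol-1 (WBGene00045401, chromosome V, 13979462 to 13980907) and argk-1 (WBGene00009706, chromosome V, 16103894 to 16105952). Among 24 intracellular pathogen response genes, 16 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 5.59e-49, adjusted p = 0.000871 with an estimated correlation). Their median log2 difference was 4.59, also with members at 0 counts in a group set to their bound of 3 counts, and 3.67 without these 2 members. Among 31 innate immune effectors, 14 were higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 1.37e-14, adjusted p = 0.0222 with an estimated correlation). They included the lysozyme genes lys-4 (2.27 ± 0.26) and lys-8 (0.98 ± 0.11) and dod-24 (1.96 ± 0.25). Of 34 major sperm proteins, 0 were higher and 28 lower (0 and 30 adjusted over the list alone, camera adjusted p = 4.98e-48, adjusted p = 0.0296 with an estimated correlation), for example msp-10 (-1.79 ± 0.20) and msp-50 (-1.75 ± 0.18). Among 24 sperm genes, 0 were higher and 9 lower (0 and 13 adjusted over the list alone, camera adjusted p = 1.01e-09, adjusted p = 0.0671 with an estimated correlation), for example gsp-3 (-1.59 ± 0.19). Of 31 fatty acid oxidation genes, 1 were higher and 12 lower (2 and 14 adjusted over the list alone, camera adjusted p = 4.58e-07, adjusted p = 0.00631 with an estimated correlation). They included acdh-1 (-1.79 ± 0.19), acox-1.2 (-1.48 ± 0.20) and hach-1 (-0.66 ± 0.10). Of 12 iron storage and transport genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.000403, adjusted p = 0.157 with an estimated correlation). The haem carrier gene hrg-3 (3.30 ± 0.31) and the haem signalling gene hrg-7 (1.18 ± 0.15) were higher. Among 22 intestine genes, 9 were higher and 3 lower (11 and 6 adjusted over the list alone, camera adjusted p = 0.00165, adjusted p = 0.343 with an estimated correlation). The proteases cpr-4 (1.21 ± 0.11) and asp-3 (1.21 ± 0.14) were higher. Among 65 UDP-glucuronosyl transferases, 13 were higher and 4 lower (17 and 5 adjusted over the list alone, camera adjusted p = 0.00411, adjusted p = 0.54 with an estimated correlation), including ugt-13 (1.95 ± 0.14) and ugt-25 (2.02 ± 0.17). Of 136 collagens, 1 were higher and 14 lower (1 and 22 adjusted over the list alone, camera adjusted p = 7.08e-08, adjusted p = 0.222 with an estimated correlation), including col-129 (-1.4 ± 0.12). In total 767 genes were higher and 443 lower, or 961 and 1048 with the length trend removed and the replicate block. Leaving out 1 library gave 660 without N2 control replicate 1, 530 without N2 control replicate 2 and 783 without sgk-1 control replicate 2.

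After cold, the sgk-1 strain had lower hypoxia response and fatty acid oxidation genes than N2, while the other lists below did not pass with an estimated correlation. Among 17 hypoxia response genes, 0 were higher and 8 lower (0 and 9 adjusted over the list alone, camera adjusted p = 4.45e-15, adjusted p = 0.000883 with an estimated correlation). They included rhy-1 (-2.65 ± 0.14), nhr-57 (-1.99 ± 0.16), cah-4 (-1.96 ± 0.10) and cysl-2 (-1.82 ± 0.10). The osmotic stress gene gpdh-1 (4.41 ± 0.25), a glycerol-3-phosphate dehydrogenase, was higher. So were argk-1 (4.71 ± 0.25), asp-12 (4.60 ± 0.22), hrg-2 (3.96 ± 0.25) and gsto-1 (3.85 ± 0.42), while asm-3 (-5.11 ± 0.34), cyp-13B1 (-4.05 ± 0.36), amt-4 (-4.07 ± 0.25) and spp-17 (-3.91 ± 0.27) were lower. Of 6 yolk proteins, 0 were higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.000857, adjusted p = 0.473 with an estimated correlation), with vit-1 (-3.25 ± 0.41) and vit-3 (-2.27 ± 0.37). Of 24 intracellular pathogen response genes, 12 were higher and 3 lower (14 and 3 adjusted over the list alone, camera adjusted p = 2.54e-09, adjusted p = 0.0625 with an estimated correlation), for example eol-1 (4.63 ± 0.30) and pals-6 (4.58 ± 0.50). Among 12 iron storage and transport genes, 6 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.000208, adjusted p = 0.167 with an estimated correlation). The ferritin genes ftn-1 (2.04 ± 0.29) and ftn-2 (1.06 ± 0.14) were higher. Among 31 fatty acid oxidation genes, 3 were higher and 14 lower (4 and 16 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.0265 with an estimated correlation), with acdh-1 (-2.3 ± 0.19) lower and hacd-1 (1.94 ± 0.18) higher. Of 23 lipase and lipid droplet genes, 7 were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.426 with an estimated correlation). They included lbp-3 (1.74 ± 0.17), lipl-5 (-2.3 ± 0.32) and lipl-4 (3.35 ± 0.46), the last at 4.44 without N2 cold replicate 1. Among 24 cuticle and moulting genes, 10 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.000575, adjusted p = 0.167 with an estimated correlation), for example sqt-3 (0.86 ± 0.15). Of 65 UDP-glucuronosyl transferases, 23 were higher and 7 lower (26 and 8 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.473 with an estimated correlation), for example ugt-16 (2.62 ± 0.20). Of 221 nuclear hormone receptors, 51 were higher and 3 lower (60 and 6 adjusted over the list alone, camera adjusted p = 0.000871, adjusted p = 0.249 with an estimated correlation), including nhr-74 (3.22 ± 0.23). Altogether 1520 genes were higher and 636 lower, which turned to 1746 and 2439 with the length trend removed and the replicate block. Counts changed to 1193 without N2 cold replicate 1, 1169 without N2 cold replicate 2, 1216 without sgk-1 cold replicate 1 and 1241 without sgk-1 cold replicate 2.

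The pqm-1-labelled control libraries had high collagen and cuticle transcripts, while the other lists below did not pass with an estimated correlation. Among 136 collagens, 70 were higher and 11 lower (79 and 16 adjusted over the list alone, camera adjusted p = 1.48e-32, adjusted p = 0.0155 with an estimated correlation). They included col-167 (3.05 ± 0.16), col-10 (2.1 ± 0.14), col-144 (2.52 ± 0.18) and col-147 (3.68 ± 0.28). Of 24 cuticle and moulting genes, 20 were higher and 1 lower (22 and 2 adjusted over the list alone, camera adjusted p = 8.68e-30, adjusted p = 0.000753 with an estimated correlation). They included sqt-1 (2.93 ± 0.25), sqt-3 (1.89 ± 0.16), dpy-5 (2.58 ± 0.22) and lon-3 (2.48 ± 0.24). Among 34 major sperm proteins, 26 were higher and 0 lower (28 and 0 adjusted over the list alone, camera adjusted p = 2.8e-28, adjusted p = 0.117 with an estimated correlation), for example msp-19 (1.33 ± 0.17) and msp-65 (1.37 ± 0.18). Of 24 sperm genes, 13 were higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 9.27e-12, adjusted p = 0.0527 with an estimated correlation). Examples were sss-1 (1.56 ± 0.19), spe-15 (1.13 ± 0.17) and gsp-3 (1.17 ± 0.18). Of 17 pharynx genes, 6 were higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.000912, adjusted p = 0.14 with an estimated correlation), with abu-14 (2.49 ± 0.36) and tnt-4 (1.27 ± 0.20) higher. Yolk transcripts took 3.75% and 6.09% of counts in these libraries against 8.64% and 7.38% in N2 control libraries. Among 6 yolk proteins, 0 were higher and 0 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.00228, adjusted p = 0.582 with an estimated correlation), or 1 lower with the replicate block. Other genes that were higher included B0205.13 (4.91 ± 0.30), the channel gene acd-1 (3.43 ± 0.16), the haem-response gene hrg-2 (3.33 ± 0.25) and cyp-33C8 (3.03 ± 0.25). The lower ones included pud-3 (-5.07 ± 0.16), pud-4 (-4.77 ± 0.17), the lectin gene clec-190 (-2.94 ± 0.23), acdh-2 (-2.13 ± 0.25) and pqm-1 itself (-1.41 ± 0.18). Here 1178 genes were higher and 268 lower, or 1383 and 877 with the length trend removed and the replicate block. Calls in total numbered 634 without N2 control replicate 1, 767 without N2 control replicate 2, 868 without pqm-1-labelled control replicate 1 and 816 without pqm-1-labelled control replicate 2.

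Collagen and cuticle transcripts were also higher than in N2, and hypoxia response transcripts lower, in pqm-1-labelled libraries after cold, while the other lists below did not pass with an estimated correlation. Of 136 collagens, 76 were higher and 9 lower (84 and 13 adjusted over the list alone, camera adjusted p = 4.53e-27, adjusted p = 0.0226 with an estimated correlation). They included col-167 (2.94 ± 0.16), col-113 (3.23 ± 0.21) and col-10 (2.26 ± 0.14). Among 24 cuticle and moulting genes, 17 were higher and 0 lower (18 and 0 adjusted over the list alone, camera adjusted p = 6.42e-11, adjusted p = 0.0197 with an estimated correlation), for example dpy-5 (1.90 ± 0.21) and sqt-2 (2.11 ± 0.26). Of 34 major sperm proteins, 26 were higher and 0 lower (29 and 0 adjusted over the list alone, camera adjusted p = 1.44e-13, adjusted p = 0.333 with an estimated correlation), for example msp-10 (1.3 ± 0.18). Among 24 sperm genes, 11 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 3.24e-05, adjusted p = 0.305 with an estimated correlation), for example ssp-10 (0.97 ± 0.19). Yolk transcripts made up 3% and 3.59% of counts, against 7.1% and 7.17% in N2 cold libraries. Of 6 yolk proteins, 0 were higher and 4 lower (0 and 6 adjusted over the list alone, camera adjusted p = 4.71e-05, adjusted p = 0.51 with an estimated correlation), for example vit-1 (-1.98 ± 0.39). Of 17 hypoxia response genes, 1 were higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 1.49e-05, adjusted p = 0.0197 with an estimated correlation). They included rhy-1 (-2.47 ± 0.14), cysl-2 (-1.72 ± 0.10) and nhr-57 (-1.66 ± 0.16). The pump gene catp-2 (11.30 ± 0.40), nhx-6 (6.73 ± 0.43) and dod-3 (5.22 ± 0.40) were higher. That of catp-2 rests on near-zero N2 counts (0.133 ± 0.15 CPM) and was 13.53 without N2 cold replicate 2. The genes pud-3 (-4.68 ± 0.17), pud-4 (-4.23 ± 0.17), parg-2 (-2.60 ± 0.17), the peptidase gene dpf-6 (-3.22 ± 0.19) and the asparagine synthetase gene asns-2 (-2.39 ± 0.16) were lower. Among 65 UDP-glucuronosyl transferases, 12 were higher and 16 lower (14 and 17 adjusted over the list alone, camera adjusted p = 0.000644, adjusted p = 0.539 with an estimated correlation), including ugt-25 (-2.35 ± 0.18). Among 19 osmotic and epidermal stress genes, 1 were higher and 6 lower (2 and 9 adjusted over the list alone, camera adjusted p = 0.00355, adjusted p = 0.51 with an estimated correlation), including nlp-31 (-1.66 ± 0.32). Of 25 endoplasmic reticulum chaperones, 0 were higher and 4 lower (0 and 10 adjusted over the list alone, camera adjusted p = 5.05e-05, adjusted p = 0.51 with an estimated correlation). With the replicate block 9 were lower, and dnj-7 (-0.57 ± 0.10) was lower. There were 1577 genes higher and 609 lower. The lower genes became 1091 under the replicate block, and the split became 1916 higher and 2472 lower with the length trend removed as well. Dropping single libraries left 1030 without N2 cold replicate 1, 984 without N2 cold replicate 2, 1077 without pqm-1-labelled cold replicate 1 and 1179 without pqm-1-labelled cold replicate 2.

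**Figure D3:**
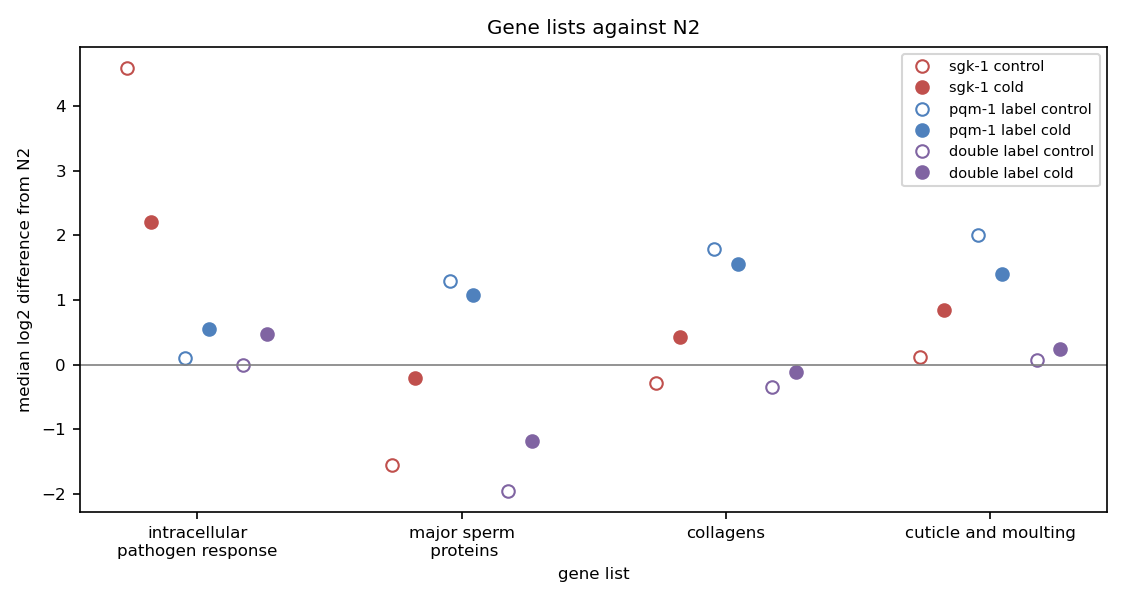
Median log2 difference from N2 (vertical axis) of 4 gene lists in control (open symbols) and cold (filled symbols) libraries of the sgk-1 strain, the pqm-1 label and the double mutant label; each point is the median over the tested members of a list. Pathogen response genes lie at 4.59 and 2.2 in the sgk-1 strain, collagens at 1.79 (1.71 with members at 0 counts in a group set to their bound) and 1.56 in the pqm-1 label, and major sperm proteins at -1.95 and -1.19 in the double mutant label.

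Double-labelled control libraries had low sperm and fatty acid oxidation genes and high innate immune genes relative to N2. Among 34 major sperm proteins, 0 were higher and 29 lower (0 and 31 adjusted over the list alone, camera adjusted p = 3.59e-71, adjusted p = 0.0148 with an estimated correlation), for example msp-10 (-2.19 ± 0.21) and msp-56 (-2.01 ± 0.20). Of 24 sperm genes, 0 were higher and 11 lower (0 and 12 adjusted over the list alone, camera adjusted p = 5.15e-13, adjusted p = 0.0476 with an estimated correlation), for example gsp-3 (-2.0 ± 0.20). Of 31 innate immune effectors, 12 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 3.96e-10, adjusted p = 0.0483 with an estimated correlation). They included lys-4 (2.51 ± 0.26), lys-8 (1.17 ± 0.11) and C17H12.8 (2.38 ± 0.26). Of 31 fatty acid oxidation genes, 2 were higher and 11 lower (2 and 12 adjusted over the list alone, camera adjusted p = 3.98e-08, adjusted p = 0.00705 with an estimated correlation), with acdh-2 (-2.70 ± 0.26) lower and ech-9 (3.35 ± 0.37) higher. Of 12 iron storage and transport genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 5.99e-05, adjusted p = 0.104 with an estimated correlation), with hrg-3 (3.19 ± 0.31) higher. Further higher genes were argk-1 (8.85 ± 0.35), asp-12 (4.49 ± 0.23), clec-169 (3.81 ± 0.32), lipl-4 (4.1 ± 0.49), cth-1 (3.09 ± 0.18) and pho-9 (3.01 ± 0.20). Further lower genes were pud-3 (-4.06 ± 0.15), pud-4 (-4.02 ± 0.16), lips-14 (-3.43 ± 0.38), dhs-26 (-2.75 ± 0.30) and ugt-53 (-2.54 ± 0.23). Among 136 collagens, 2 were higher and 20 lower (4 and 33 adjusted over the list alone, camera adjusted p = 3.06e-09, adjusted p = 0.167 with an estimated correlation), including col-129 (-2.2 ± 0.13). In sum 485 genes were higher and 524 lower, but 531 and 482 with RLE size factors and 812 and 725 in DESeq2. Only 75 were higher and 62 lower when the compared groups alone were fitted. Leaving out 1 library gave 583 without N2 control replicate 1, 409 without N2 control replicate 2 and 1739 without double-labelled control replicate 2, where N2 control replicate 2 left 208 higher and 201 lower.

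Compared with the sgk-1 strain, double-labelled control libraries had low pathogen response genes. Among 24 intracellular pathogen response genes, 0 were higher and 17 lower (0 and 19 adjusted over the list alone, camera adjusted p = 4.78e-106, adjusted p = 3.55e-05 with an estimated correlation), for example pals-26 (-4.73 ± 0.34) and pals-14 (-6.05 ± 0.46). Outside the list, ddn-1 (-5.73 ± 0.29), irg-5 (-3.91 ± 0.34), B0507.8 (-8.56 ± 0.39) and the F-box gene fbxa-182 (-3.28 ± 0.24) were lower too, B0507.8 at -9.85 without double-labelled control replicate 1. Higher were gba-4 (4.44 ± 0.52), spp-17 (3.89 ± 0.27) and txt-4 (2.67 ± 0.17). This comparison had 66 genes higher and 166 lower. Leaving out 1 library gave 432 without double-labelled control replicate 2 and 134 without sgk-1 control replicate 1.

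After cold, double-labelled libraries differed from N2 by high intestinal, lipid and iron genes and low hypoxia response genes. Of 22 intestine genes, 15 were higher and 0 lower (16 and 3 adjusted over the list alone, camera adjusted p = 2.27e-13, adjusted p = 0.0387 with an estimated correlation). They included cpr-4 (1.55 ± 0.11), pept-1 (1.97 ± 0.15) and acox-1.4 (1.34 ± 0.17). Among 23 lipase and lipid droplet genes, 9 were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 1.26e-06, adjusted p = 0.0438 with an estimated correlation), for example lbp-3 (2.04 ± 0.17) and dhs-3 (0.98 ± 0.12). Among 12 iron storage and transport genes, 7 were higher and 0 lower (7 and 1 adjusted over the list alone, camera adjusted p = 6.3e-09, adjusted p = 0.0387 with an estimated correlation), or 1 lower with the replicate block. Examples were fpn-1.2 (3.76 ± 0.32) and hrg-7 (2.15 ± 0.15). Of 152 C-type lectins, 38 were higher and 4 lower (46 and 8 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.0387 with an estimated correlation), including clec-166 (2.64 ± 0.21) and clec-62 (1.27 ± 0.12). Among 31 innate immune effectors, 12 were higher and 4 lower (16 and 4 adjusted over the list alone, camera adjusted p = 8.9e-08, adjusted p = 0.0562 with an estimated correlation), with lys-2 (3.85 ± 0.27) higher and irg-5 (-3.59 ± 0.32) lower. Of 23 DAF-16 repressed genes, 8 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.0438 with an estimated correlation), including asp-3 (1.62 ± 0.14). Among 17 hypoxia response genes, 0 were higher and 8 lower (0 and 10 adjusted over the list alone, camera adjusted p = 3.88e-12, adjusted p = 0.00223 with an estimated correlation). They included cysl-2 (-2.1 ± 0.10), rhy-1 (-2.58 ± 0.14) and nhr-57 (-2.54 ± 0.16). Of 34 major sperm proteins, 0 were higher and 24 lower (0 and 30 adjusted over the list alone, camera adjusted p = 1.41e-22, adjusted p = 0.091 with an estimated correlation), with msp-50 (-1.27 ± 0.18). Also higher were catp-2 (8.25 ± 0.38), nhx-6 (5.28 ± 0.40), dod-3 (4.63 ± 0.39), elo-2 (1.61 ± 0.13), argk-1 (4.91 ± 0.25) and asp-12 (4.44 ± 0.22), with catp-2 at 10.47 without N2 cold replicate 2. Lower were pud-4 (-4.06 ± 0.17), the tyrosine aminotransferase gene tatn-1 (-3.21 ± 0.29), pho-9 (-2.99 ± 0.19) and the chitinase gene cht-1 (-2.82 ± 0.19). The totals were 1053 higher and 637 lower, or 1188 and 1131 with the length trend removed and the replicate block. This total became 1034 without N2 cold replicate 1, 1048 without N2 cold replicate 2 and 1083 without double-labelled cold replicate 2.

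Against the sgk-1 strain after cold, double-labelled libraries were higher in dod-3 (6.98 ± 0.45), nhx-6 (6.00 ± 0.42), hrg-4 (3.81 ± 0.46), acd-1 (3.43 ± 0.15), lys-2 (2.94 ± 0.26) and the protease gene cpr-1 (2.32 ± 0.22). They were lower in gpdh-1 (-3.58 ± 0.23), the fucosyltransferase gene fut-2 (-3.30 ± 0.47), ddn-1 (-3.81 ± 0.27) and B0507.8 (-4.40 ± 0.30). Of 24 intracellular pathogen response genes, 0 were higher and 9 lower (0 and 12 adjusted over the list alone, camera adjusted p = 1.26e-12, adjusted p = 0.0514 with an estimated correlation), for example eol-1 (-3.43 ± 0.27) and pals-6 (-3.69 ± 0.46). Among 34 major sperm proteins, 0 were higher and 17 lower (0 and 30 adjusted over the list alone, camera adjusted p = 6.4e-17, adjusted p = 0.226 with an estimated correlation), for example msp-56 (-1.12 ± 0.19). Among 6 yolk proteins, 2 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.000119, adjusted p = 0.328 with an estimated correlation), for example vit-1 (2.47 ± 0.40). Among 22 intestine genes, 8 were higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 8.63e-06, adjusted p = 0.226 with an estimated correlation), including ges-1 (0.83 ± 0.10). Of 136 collagens, 1 were higher and 16 lower (2 and 22 adjusted over the list alone, camera adjusted p = 0.000161, adjusted p = 0.328 with an estimated correlation). This gave 472 genes higher and 762 lower, or 927 and 1003 with the length trend removed and the replicate block. Leaving out 1 library gave 720 without double-labelled cold replicate 1, 501 without double-labelled cold replicate 2, 507 without sgk-1 cold replicate 1 and 603 without sgk-1 cold replicate 2. Without double-labelled cold replicate 2 the majority turned, to 269 higher and 232 lower.

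Whether changes of the sgk-1 strain recur in the double mutant label was measured in libraries other than those used to select them. The 767 genes higher in the sgk-1 strain without cold had a median of 0.88 against N2 after cold in that strain and 0.65 in double-labelled libraries, and 129 of them were lower in double-labelled than in sgk-1 cold libraries (33.5 if calls were independent) while 75 were higher still (20.7). The 443 genes lower without cold had medians of -0.24 and -0.61 after cold, and 65 were higher in double-labelled libraries (12 if independent) while 108 were lower still (19.3). Of 1520 genes higher in sgk-1 cold libraries, 83 were lower in the double mutant label without cold (14.5 if independent) and 7 higher (5.75). Of 636 lower genes, 27 were higher (2.4 if independent) and 21 lower (6.05). The 194 genes called in the opposing direction after cold became 118 without N2 control replicate 1, 105 without N2 control replicate 2, 124 without double-labelled cold replicate 1, 108 without double-labelled cold replicate 2, 111 without sgk-1 cold replicate 1 and 116 without sgk-1 cold replicate 2 when 1 library was left out.

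Differences from N2 in the sgk-1 strain and in the double mutant label shared 621 calls of one direction without cold and 995 with cold, where independent lists would share 34.6 and 115. The pqm-1 and double mutant labels shared 127 and 602 such calls (40.8 and 117), and the sgk-1 strain and the pqm-1 label 150 and 628 (58.5 and 159). The same N2 libraries served both strains of a pair. Across genes, which are not independent replicates, differences of log2 CPM from N2 had covariances of 0.216 and 0.236 (without and with cold) for the first pair, 0.019 and 0.133 for the second and 0.032 and 0.153 for the third. With 1 N2 library for each strain, a comparison added after the data were seen, they were 0.17 and 0.203, -0.027 and 0.099, and -0.013 and 0.12.

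Differences in cold response between strains were tested directly. Hypoxia response genes responded less in each other strain than in N2. Of 17 hypoxia response genes, 0 were higher and 5 lower (0 and 7 adjusted over the list alone, camera adjusted p = 7.99e-16, adjusted p = 0.000794 with an estimated correlation) in the sgk-1 strain. They included cah-4 (-2.45 ± 0.13), rhy-1 (-2.28 ± 0.19), nhr-57 (-2.13 ± 0.23) and cysl-2 (-2.01 ± 0.14). Among 17 hypoxia response genes, 0 were higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 1.05e-10, adjusted p = 0.00301 with an estimated correlation) in pqm-1-labelled libraries, with rhy-1 (-2.18 ± 0.19) and cysl-2 (-1.83 ± 0.14). The member cah-4 is an exception there, with a cold response of 1.88 ± 0.10 against 1.67 ± 0.10 in N2. Of 17 hypoxia response genes, 0 were higher and 5 lower (1 and 6 adjusted over the list alone, camera adjusted p = 2.43e-09, adjusted p = 0.00482 with an estimated correlation) in double-labelled libraries, with rhy-1 (-2.04 ± 0.19) and cysl-2 (-2.09 ± 0.14). At the preset correlation alone, the cold response of major sperm protein and collagen genes was higher in the sgk-1 strain than in N2, where 40 collagens fell and 6 rose. Of 34 major sperm proteins, 20 were higher and 0 lower (29 and 0 adjusted over the list alone, camera adjusted p = 3.8e-24, adjusted p = 0.174 with an estimated correlation), for example msp-50 (1.44 ± 0.24). Among 136 collagens, 21 were higher and 0 lower (34 and 0 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.273 with an estimated correlation), for example col-167 (1.83 ± 0.22). The response of pqm-1 itself was lower in the sgk-1 strain (-2.71 ± 0.24), that of the osmotic stress gene gpdh-1 higher (3.09 ± 0.31), and that of pho-9 (-5.35 ± 0.27) lower. The gene dod-3 rose more than in N2 in pqm-1-labelled (5.0 ± 0.52) and double-labelled libraries (4.57 ± 0.53). The fall of hrg-4 was smaller there than in N2, by 4.68 ± 0.66 and 4.75 ± 0.65 (7.24 and 7.31 without N2 cold replicate 2). The elongase gene elo-2 fell less in double-labelled libraries (1.54 ± 0.17). The response of pathogen response genes was higher in double-labelled libraries than in the sgk-1 strain. Among 24 intracellular pathogen response genes, 6 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 7.35e-23, adjusted p = 0.0145 with an estimated correlation), for example pals-26 (4.14 ± 0.42). The numbers of genes with a different response were 736 (sgk-1 against N2, 428 higher), 368 (pqm-1 label, 222 higher), 475 (double mutant label, 311 higher) and 211 (double mutant label against sgk-1, 155 higher). Leaving out 1 library gave, for the sgk-1 strain against N2, 473 without N2 control replicate 1, 374 without N2 control replicate 2, 387 without N2 cold replicate 1, 450 without N2 cold replicate 2, 457 without sgk-1 control replicate 2, 395 without sgk-1 cold replicate 1 and 418 without sgk-1 cold replicate 2. For the pqm-1 label it gave 218 without N2 control replicate 1, 208 without N2 control replicate 2, 200 without N2 cold replicate 1, 242 without N2 cold replicate 2, 218 without pqm-1-labelled control replicate 2 and 243 without pqm-1-labelled cold replicate 1. For the double mutant label it gave 300 without N2 control replicate 1, 255 without N2 control replicate 2, 282 without N2 cold replicate 1, 298 without N2 cold replicate 2 and 295 without double-labelled cold replicate 2. Against the sgk-1 strain the double mutant label gave 528 without double-labelled control replicate 2, 118 without double-labelled cold replicate 1, 112 without double-labelled cold replicate 2, 89 without sgk-1 cold replicate 1 and 89 without sgk-1 cold replicate 2.

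**Figure D4:**
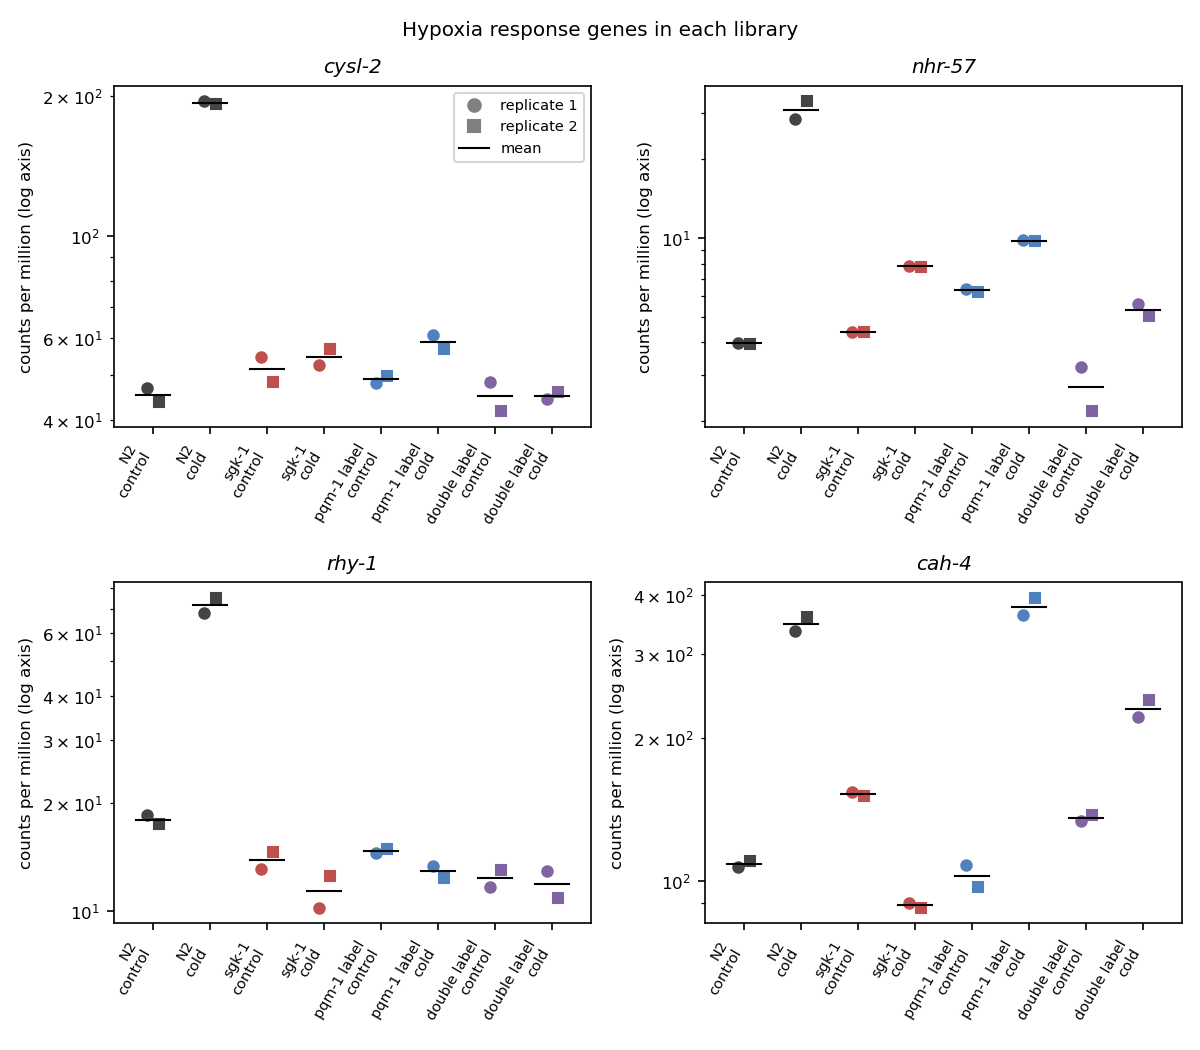
CPM (log axis) of cysl-2, nhr-57, rhy-1 and cah-4 in each of the 16 libraries, by group; circles are replicate 1, squares replicate 2, and the bar is the mean of the 2 libraries. In N2 the log2 differences of cold from control libraries are 2.1, 2.96, 1.99 and 1.67, and cah-4 also lies higher with cold in the pqm-1 label, by 1.88.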

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

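Of the tests below, those on the age of the animals, on the collagens and the pathogen response genes of the double mutant label, on pals paralogs, on a strain-wide infection or variant and on the N2 cold cultures were chosen after the result was seen.

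Cold responses that differed between strains by a test of the difference itself are listed first. The response differed from that of N2 in 736 genes in the sgk-1 strain, 368 in pqm-1-labelled and 475 in double-labelled libraries, and between the double mutant label and the sgk-1 strain in 211 genes. Without 1 library these counts ran from 374 to 702, 200 to 278, 255 to 692 and 89 to 528. In the sgk-1 strain the log2 response was lower than in N2 for pho-9 (-5.35), pqm-1 (-2.71), cah-4 (-2.45), rhy-1 (-2.28), nhr-57 (-2.13) and cysl-2 (-2.01), and higher for gpdh-1 (3.09), col-167 (1.83) and msp-50 (1.44). In pqm-1-labelled libraries it was lower for rhy-1 (-2.18) and cysl-2 (-1.83) and higher for dod-3 (5.0) and hrg-4 (4.68, a smaller fall than in N2). In double-labelled libraries it was lower for cysl-2 (-2.09) and rhy-1 (-2.04) and higher for dod-3 (4.57) and, as smaller falls, hrg-4 (4.75) and elo-2 (1.54). Against the sgk-1 strain, the response of pals-26 was higher in double-labelled libraries (4.14). Median differences of gene lists were -0.43, -0.34 and -0.29 for hypoxia response genes in the sgk-1, pqm-1-labelled and double-labelled libraries against N2, 0.58 for collagens (0.61 without members at 0 counts in a group) and 1.34 for major sperm proteins in the sgk-1 strain against N2 (adjusted p = 0.273 and 0.174 with an estimated correlation, so neither passed it), and 2.36 (1.86 without such members) for pathogen response genes in the double mutant label against the sgk-1 strain.

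Collagen and cuticle genes were higher than in N2 in pqm-1-labelled libraries in both conditions, as were sperm lists at the preset correlation alone (adjusted p = 0.0527 to 0.333 with an estimated one). A trend over gene length does not account for it, since 90 of 90 collagens and cuticle genes called higher without cold stayed called with the trend removed, and the collagen median was then 1.69. If the labels hold, collagens of the double mutant label argue against a pqm-1 genotype effect alike with and without sgk-1. Their median relative to the sgk-1 strain was -0.45 with cold and 0.02 without. Younger animals cannot be told apart from a variant of the pqm-1-labelled strain or a genotype effect that needs sgk-1, both untested. The medians of yolk genes and of oocyte and eggshell genes were below 0 in 4 of 4 cases, as younger animals would give, but none passed with an estimated correlation (adjusted p = 0.51 to 0.75).

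Intracellular pathogen response genes were high in the sgk-1 strain and low in the double mutant label relative to it. Infection of a single culture does not account for the high level, since 4 of 4 libraries of the sgk-1 strain lay above both N2 libraries of their condition. Reads shared between pals copies do not either, as the 9 members other than pals genes had a median of 1.52 against N2 without cold and 5 of them were called. An effect of the sgk-1 genotype that is alike with and without the pqm-1 label is argued against by the double mutant label, which also had few sgk-1 transcripts but lay at a median of -4.83 relative to the sgk-1 strain without cold (-4.67 without members at 0 counts). An infection or a linked variant carried by the whole sgk-1 strain and an effect of the genotype that the pqm-1 label removes cannot be told apart here, because the median after cold (2.2, or 1.8 without members at 0 counts, adjusted p = 0.0625 with an estimated correlation) is what each would give.

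Hypoxia response genes were raised more by cold in N2 than in the other strains. Against a single aberrant library, 6 of 6 medians of the difference by replicate number were below 0, but strains shared N2 libraries. Gene length is excluded as the whole cause, with 6 of 17 members still called lower in the sgk-1 strain and a median of -0.52 once the trend was removed. Handling of the N2 cold cultures does not account for cah-4, whose cold response was higher by 2.66 in pqm-1-labelled than in sgk-1 libraries, as 1 of 2 members called in that difference. For the list as a whole, such handling and an effect of each mutation cannot be told apart, because every other strain had a median cold response of at most 0.08, against 0.38 in N2, as each would give.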

How the results depend on the processing

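Gene length, the list tests, the overlap and the double mutant comparison without single libraries were chosen after the data were seen, and the other refits before. Scaling by RLE size factors kept all 16 counts of called genes within 1.5 times, and the replicate block kept these and the list, overlap and double mutant counts there, although it raised the lower genes of the pqm-1 label after cold from 609 to 1091. It changed the call of none of the 96 list results printed. In N2 hsp-4, not called at 0.02, went to -0.03 with the block and the length trend removed and to between -0.05 and 0.09 without single libraries. For genes named as called nothing is learned from the refits, because they were picked for keeping their call. Over all called genes, 42.2% to 69.1% by contrast lost their call or direction without some library. Of the printed list results, 64 lost their call with an estimated correlation.

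Asking for a log2 fold change of at least 1 lowered counts by construction, to 2033 (cold in N2), 1784 (sgk-1), 1913 (pqm-1 label) and 1429 (double mutant label), to 728 (sgk-1 against N2, control), 672 (double mutant label against N2, control), 1215 (sgk-1, cold), 1270 (pqm-1 label, cold), 1029 (double mutant label, cold) and 736 (double mutant label against sgk-1, cold), and to 628 shared genes and 102 opposing calls of the double mutant comparison. Fitting only the compared groups gave 5753 (cold in N2), 1061 (cold, double mutant label), 137 and 45 (double mutant label against N2 and against sgk-1, control), 5725, 5514 and 2649 (sgk-1, pqm-1 and double mutant labels against N2, cold), 2988 (double mutant label against sgk-1, cold), and 597, 308 and 75 for the response differences of the pqm-1 label, the double mutant label and the double mutant label against sgk-1. Without the filter the counts were 1547 and 568 (double mutant label against N2 and sgk-1, control), 3695 (pqm-1 label, cold), 1887 (double mutant label against sgk-1, cold), and 1326, 737, 859 and 618 for the response differences of sgk-1, the pqm-1 label, the double mutant label and the last against sgk-1. DESeq2 gave 1537 and 506 for the double mutant label against N2 and sgk-1 (control) and 1147, 671, 816 and 439 for the response differences in the same order. The block together with removal of the length trend gave 4305 (cold, double mutant label), 2009, 2260 and 410 (sgk-1 and pqm-1 label against N2 and double mutant label against sgk-1, control), 4185, 4388 and 1930 (the same after cold), 614, 780 and 390 (response differences of the pqm-1 label, the double mutant label and the last against sgk-1) and 369 opposing calls. With an estimated correlation 32 list tests passed. Apart from the minimum fold, the cause was not tested.

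Without 1 library, counts ran from 2309 to 2375 (cold in N2, 3250 with all), 1777 to 2413 (cold in sgk-1, 3004), 2287 to 2487 (pqm-1 label, 3272) and 1636 to 4589 (double mutant label, 2594). Against N2 without cold they ran from 530 to 828 (sgk-1, 1210), 634 to 868 (pqm-1 label, 1446) and 409 to 1739 (double mutant label, 1009), and for the double mutant label against sgk-1 from 134 to 432 (232). After cold they ran from 1169 to 1241 (sgk-1, 2156), 984 to 1179 (pqm-1 label, 2186), 1034 to 1196 (double mutant label, 1690) and 501 to 720 (double mutant label against sgk-1, 1234). Response differences ran from 374 to 702 (sgk-1, 736), 200 to 278 (pqm-1 label, 368), 255 to 692 (double mutant label, 475) and 89 to 528 (the last against sgk-1, 211). List tests ran from 229 to 281 (242), shared genes from 955 to 1366 (1256) and opposing calls from 105 to 160 (194). Depth limited values near 0.0619 CPM or less. Simulated changes of a log2 value of 1 were recovered in 68 of 100 genes with a mean of at least 1 CPM for cold in N2.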

Other observations

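The groups, genes and comparisons of this part were chosen after the results were seen, from the lists, genes and contrasts fixed before. The genes that part the strains were searched for afterwards. In N2, DAF-16 repressed genes passed with an estimated correlation and the 2 lists after them did not. Among 23 DAF-16 repressed genes, 3 were higher and 10 lower (4 and 10 adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.0467 with an estimated correlation). They included the metallothionein gene mtl-2 (-1.49 ± 0.15) and the delta-9 desaturase gene fat-6 (-1.56 ± 0.21). Of 23 lipase and lipid droplet genes, 0 were higher and 7 lower (1 and 9 adjusted over the list alone, camera adjusted p = 0.0074, adjusted p = 0.294 with an estimated correlation), or 1 higher with the replicate block. The lipid droplet gene dhs-3 (-1.73 ± 0.13), the lysosomal lipase gene lipl-1 (-2.18 ± 0.29) and the triglyceride synthesis gene dgat-2 (-1.19 ± 0.22) were lower. Of 41 nuclear respiratory chain genes, 0 were higher and 6 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.00599, adjusted p = 0.48 with an estimated correlation), with gas-1 (-0.97 ± 0.11) and ucr-2.2 (-0.76 ± 0.16) lower.

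Of the panel in N2, cold raised the bZIP gene zip-10 (1.59 ± 0.24) and the protease gene asp-17 (2.96 ± 0.27) and lowered the superoxide dismutase gene sod-3 (-1.62 ± 0.27). The values of daf-16 (0.25 ± 0.15), skn-1 (0.13 ± 0.19) and fat-7 (-0.44 ± 0.31) did not pass the test (edgeR adjusted p = 0.335, 0.72 and 0.401). Nor did those of the chaperone genes hsp-4 (0.02 ± 0.12), hsp-6 (-0.08 ± 0.20) and hsp-16.2 (0.59 ± 0.34, edgeR adjusted p = 0.931, 0.84 and 0.286). A further list differed from N2 after cold at the preset correlation alone. Of 9 cold-warming program genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.091 with an estimated correlation) in double-labelled libraries. They included asp-14 (1.71 ± 0.21) and cpr-8 (1.21 ± 0.11) (list median 0.14).

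The gene Y17G7B.23 (WBcel235 chromosome II, 11999203 to 12001524) lay at 3.24 to 8.11 CPM in the 4 pqm-1-labelled and 2.94 to 9.8 CPM in the 4 double-labelled libraries. It lay at no more than 0.0899 CPM in N2 and 0.0948 CPM in the sgk-1 strain. Of 17461 genes tested it was the only one whose CPM parted these 8 libraries from the other 8 by at least 1 log2 unit. In this way 16 genes parted the sgk-1 and double-labelled libraries from the rest and 0 parted the N2 and double-labelled ones. Chance would part 0.0155% of genes (2.7) if a separation of any size counted. This does not gauge a gap as wide as that of Y17G7B.23, 847 kb from pqm-1. On chromosome III, cdk-5 parted the same 8 by less (at most 19 against at least 28.4 CPM). What both say about the labels was not tested. F17E5.2 lay at 0 to 0.136 CPM in pqm-1-labelled libraries and at 11.6 to 18.6 CPM in the other 12, the double-labelled ones included.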
